A study of Mus musculus with 17 samples.

How the data were processed

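RNA sequencing was analysed from 6 samples of CD45+ cells and 11 samples of the dendritic cell line MutuDC, all from mouse. Per the submitters' processing notes, the tools named upstream were fastp, STAR, featureCounts 1.5.0-p3 and DESeq2 1.20.0, with genome build GRCm38, and versions of fastp and STAR are not given in the sources used here. The deposited counts are raw counts per Ensembl gene, whole numbers with column totals that differ between samples, and each library has its own column. The authors also made FPKM values, fragments scaled by gene length and library total. In the CD45 table they equal counts divided by the given gene length and the column total, up to 1 further factor per sample that the sources do not explain. The inverse of that factor (0.952 to 1.086) lay close to the TMM scaling factor of each sample (0.947 to 1.077) used below. FPKM in that set were thus scaled much like the counts. In the MutuDC table they use a length that is the same in all samples and is not defined. The comparisons used the counts, the FPKM served for an alternative, and tables of group means were not used because they hold no replicates. Gene symbols, coordinates and biotypes are those in the deposited tables.

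Samples were grouped by the labels. The CD45 set and MutuDC were fitted apart, with 3 against 3 samples in the first and with 1 model over EV (n = 2), Vkine, EV with LPS and Vkine with LPS (n = 3 each) in the second. Low-count genes were removed with filterByExpr on the groups, libraries were scaled by TMM, and each contrast was tested with the edgeR quasi-likelihood F test with robust estimation (edgeR 4.0.16 under R 4.3.3). Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in that comparison were called. The SE of a log2 fold change is its size divided by the square root of F. CPM come from the cpm function of edgeR with TMM-scaled library totals, given as mean and SD of the group. Log2 CPM for principal components and list means used a prior count of 2. Totals of 13814620 to 21263321 counts per library set the depth, and tests and SEs rest on the spread between replicates.

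49 gene lists of pathways, cell types and study genes, the rule for named genes and the comparisons were fixed before the data were examined. 46 lists applied to the CD45 set and 30 to MutuDC, and those with at least 5 measured members were tested (42 and 28) with camera of limma 3.58.1 at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Each list was also tested with an estimated correlation and with fry, and its members were counted both over all genes and adjusted over the list alone. Some genes belong to several lists, so results of different lists are not independent. Named genes are up to 10 per direction (5 in the interaction) with the largest fold change among called protein-coding genes with a mean log2 CPM of at least 2 and no overlap between the samples of the groups, leaving out predicted genes and receptor segments, up to 4 members with the smallest p in each list, the study genes and Vcan. Genes named outside this rule were chosen after their values were seen: they are genes that the rule names in another comparison, and mt-Co1. Overlaps of called genes were tested with Fisher's exact test, two-sided, and fold changes were correlated across genes.

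The alternatives were DESeq2 median-of-ratios and upper-quartile factors, no low-count filter and a stricter one (CPM of at least 1), DESeq2 1.42.0, a test against a fold of 1.5, limma-trend on log2 FPKM with 1 or 0.1 added, estimation without robustness, a replicate block, a fit of the compared groups alone, and leaving out each sample in turn. The block followed the replicate number in MutuDC. In the CD45 set it followed the titles and paired EV sample R1 with Vkine sample L1 and R2 with L2. Samples R1L1 and L3 were unpaired there and added nothing to the comparison. The pipeline was tested on simulated data with known changes. For the CD45 design edgeR found 0% of the genes changed by 1.5-fold, 34.3% at 2-fold and 71.2% at 4-fold with 5 false calls, and DESeq2 found 8.96%, 49.3% and 77.3% with 33 false calls. In the 5 MutuDC comparisons edgeR found 41.8% to 73.1% at 1.5-fold, 68.7% to 80.6% at 2-fold and 75.8% to 97.0% at 4-fold, with 8 to 14 false calls. GC content and transcript length were taken from the reference genome and annotation for 99.9% of tested genes. After each library's trend with them was removed, camera ran on log2 CPM instead of counts, so a list call that changed may in part reflect the test. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 under Python 3.11.15.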

Results

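The series measured RNA by sequencing in 17 mouse samples, counted over 54532 genes, to ask what versikine does to the immune microenvironment of tumours. Versikine is a fragment that proteases release from versican, a large proteoglycan of the extracellular matrix, and the labels name it Vkine. EV is the label of the comparison arm, a common abbreviation of empty vector. One set holds CD45+ cells, the white blood cells, with 3 EV samples and 3 Vkine samples. Their sample type says tumor while their source field says bone marrow, and they are called tumor CD45 samples here. Their titles are R1, R2 and R1L1 for EV and L1, L2 and L3 for Vkine, and the sources do not say what R and L mean or whether R1 and R1L1 come from 1 animal, so the 3 EV samples may not be 3 independent animals. The other set holds MutuDC, a line of mouse conventional dendritic cells, with 2 EV samples, 3 Vkine samples, 3 EV samples given LPS and 3 Vkine samples given LPS. LPS is a bacterial lipopolysaccharide that activates dendritic cells. How Vkine was given, and the dose and time of LPS, are not given in the sources used here. The labels do not say whether replicates are separate animals or cultures, so p-values measure the spread between these samples, which may in part be technical.

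Library totals were 16976460, 16450462 and 17791086 counts for EV and 13814620, 18125269 and 17141606 for Vkine in the tumor CD45 set. In MutuDC they ran from 15938185 to 21263321. Vkine replicate 1 of the tumor CD45 set stood apart: mitochondrial genes took 10.6% of its counts, against 4.80%, 5.56% and 4.32% in EV and 2.47% and 2.75% in the other Vkine samples. Its most abundant gene was mt-Co1, with 5.90% of counts. The same gene led in the EV samples with 2.63%, 2.89% and 2.48%, whereas Cxcl2 led in Vkine replicates 2 and 3 with 1.26% and 1.52%. EV replicate 2 stood apart on the first principal component of log2 CPM (counts scaled to a common library total), which took 35.7% of the variance in this set. It lay at 69.95, with the other EV samples at -0.83 and 24.99 and the Vkine samples from -45.85 to -15.73. In MutuDC the mitochondrial share moved with group: 1.36% and 1.41% in EV, 1.72% to 1.86% in Vkine, 1.73% to 1.96% in EV with LPS and 0.936% to 1.03% in Vkine with LPS. The first principal component took 37.4% of the variance in MutuDC, with Vkine at one end (36.26 to 44.68) and Vkine with LPS at the other (-39.86 to -35.19). Both EV groups lay between them.

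Vcan, the versican gene (ENSMUSG00000021614, GRCm38 chromosome 13, 89655312 to 89742509), was transcribed in the tumor CD45 samples and near the detection limit in MutuDC. It averaged 168 CPM ± 40.8 (SD, n = 3) in EV and 234 CPM ± 100 (SD, n = 3) in Vkine. The log2 fold change of 0.47 did not pass the test (adjusted p = 0.61), and Vkine replicate 1 had 120 CPM where replicates 2 and 3 had 268 and 312 CPM. In MutuDC the means of Vcan were 0.554 ± 0.0504 CPM in EV (SD, n = 2), 0.993 ± 0.275 in Vkine, 0.325 ± 0.186 in EV with LPS and 0.518 ± 0.28 in Vkine with LPS (SD, n = 3 each). Counts per gene cannot tell transcripts of the fragment from those of the whole gene.

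The comparison of tumor CD45 cells with Vkine against EV asks how versikine shapes the immune cells of the tumour. 4 genes passed the test. Saa3, an acute-phase protein gene (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), rose from 12.7 CPM ± 3.71 to 53.8 CPM ± 14.1 (SD, n = 3), a log2 fold change of 2.08 ± 0.26 (SE). Serpinb2, which encodes a plasminogen activator inhibitor (ENSMUSG00000062345, chromosome 1, 107511423 to 107535478), rose from 25.6 CPM ± 3.4 to 67.5 CPM ± 11.4. H2-Q7, a class Ib MHC gene (ENSMUSG00000060550, chromosome 17, 35439155 to 35443773), rose from 33 CPM ± 2.94 to 74.5 CPM ± 8.04, although reads may be shared with its close paralog H2-Q6 (adjusted p = 0.24). Cspg4, the gene of the NG2 proteoglycan (ENSMUSG00000032911, chromosome 9, 56865033 to 56899870), fell from 67.1 CPM ± 12.6 to 17.7 CPM ± 4.45. The adjusted p of each was 0.042, and every Vkine sample lay beyond every EV sample.

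Beyond these 4 genes, members of many immune lists lay on the higher side in Vkine without passing the test over all 14006 genes. Of 28 measured type I interferon response genes, 27 had a positive fold change (median 0.77) and 21 were called higher when adjusted over the list alone. Irf7, a transcription factor of that response, had 113 CPM ± 23.4 in EV and 212 CPM ± 20.1 in Vkine (SD, n = 3). Zbp1 had a log2 fold change of 0.70 ± 0.18 and Oasl1 of 1.19 ± 0.30. All 23 interferon gamma response genes were positive (median 0.58), 5 of them called adjusted over the list alone, with Gbp4 at 1.18 ± 0.26 and Nos2 at 1.95 ± 0.43. All 17 inflammatory cytokines were positive too (median 1.04, 6 called adjusted over the list alone), among them Ifnb1, the interferon beta gene, with 1.6 CPM ± 0.855 in EV and 10.3 CPM ± 4.3 in Vkine. Adjusted p of the 3 lists was 4.5e-20, 8.29e-13 and 7.95e-10 by camera with its preset correlation, and 0.20, 0.18 and 0.18 with an estimated correlation. EV replicate 2 had the lowest mean log2 CPM of the type I interferon list (4.64, against 5.31 and 5.63 in the other EV samples), and without it the list median was 0.50 (adjusted p = 2.96e-17).

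Cell type markers lay higher in Vkine for neutrophils and T cells. All 15 neutrophil markers were positive (median 1.62), with 10 called adjusted over the list alone. Ngp, a granule protein gene, had 1.61 CPM ± 0.485 in EV and 7.21 CPM ± 1.4 in Vkine (SD, n = 3), and the log2 fold changes of Mmp8, Lcn2 and Ltf were 2.08, 2.03 and 1.62. All 18 T cell markers were positive (median 1.29, 3 called adjusted over the list alone). Cd3e, a subunit of the T cell receptor complex, had 0.674 CPM ± 0.334 in EV and 3.26 CPM ± 0.311 in Vkine, and Trac changed by 1.78 ± 0.46. The T cell list lay at low levels in these samples. Among 11 regulatory T cell genes the median was 1.25 and 6 were called adjusted over the list alone, including Icos (1.57 ± 0.27) and Ctla4 (1.25 ± 0.23). Adjusted p was 2.58e-16, 8.11e-10 and 2.23e-08 for the 3 lists, and 0.18 for each with an estimated correlation. EV replicate 2 was lowest here too, with a mean log2 CPM of 4.96 over neutrophil markers (6.66 and 6.78 in the other EV samples) and of -0.15 over T cell markers (1.09 and 0.72). Without it the list medians were 1.27 and 1.03, and both calls were kept (adjusted p = 1.57e-26 and 4.73e-07). Cytotoxic effector genes (median 0.55, adjusted p = 0.0049, and 0.18 with an estimated correlation) included Ccl5 at 1.5 ± 0.27, and NK cell markers (0.58, 0.0028 and 0.28) included Il2rb at 1.22 ± 0.30. Without Vkine replicate 1 the NK median was 0.35 and the call ended (adjusted p = 0.145), and the list mean of Vkine replicate 3 (0.94) lay within the EV samples (0.56 to 0.95). Monocyte markers had a median of 0.59 (3 of 14 called adjusted over the list alone, including Ms4a4c at 1.02 ± 0.17 and Ly6c2 at 0.86 ± 0.16), and innate lymphoid genes of 0.70 (2 of 10, Icos and Gata3). The monocyte median was 0.27 without Vkine replicate 3 and 0.37 without EV replicate 2, and its mean log2 CPM in Vkine replicate 1 (7.85) lay within the EV samples (7.35 to 7.87). Adjusted p was 0.0013 and 9.71e-06, and 0.25 and 0.18 with an estimated correlation. Neutrophil precursor genes (median 1.16, adjusted p = 0.0097 by camera) and plasma cell genes (0.41, 0.048) were also called higher, but not with an estimated correlation. The plasma cell median was 0.21 without Vkine replicate 3.

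Genes of dendritic cells, which the series title names, lay on the same side. 15 of 17 cDC1 markers, genes of the cross-presenting conventional dendritic cell, were positive (median 0.44), but Flt3 (0.95 ± 0.22) was the sole member called adjusted over the list alone, and without EV replicate 2 the median was 0.27. Xcr1 had a log2 fold change of 1.15 ± 0.38 (adjusted p = 0.31) and Batf3 of 0.66 ± 0.41 (adjusted p = 0.55). Mature migratory DC genes had a median of 0.68, with Fscn1 at 0.82 ± 0.24 and Ccr7 at 1.70 ± 0.50, and 5 of 18 were called adjusted over the list alone, although its mean log2 CPM in Vkine replicate 1 (4.84) lay within the EV samples (4.21 to 4.98). The class II presentation list had a median of 0.61 (0.38 without EV replicate 2) and its class I counterpart 0.26, H2-Q7 being the single member of either called over all genes. Adjusted p of these 4 lists was 0.0013, 1.44e-06, 0.00065 and 6.88e-07, and 0.18, 0.26, 0.28 and 0.18 with an estimated correlation. The 11 cDC2 markers were not called (adjusted p = 0.70), with a median of 0.19 although the test pointed down. That median was -0.05 without EV replicate 2, -0.02 without Vkine replicate 3 and 0.29 without EV replicate 1. Plasmacytoid DC genes, with 4 measured, were too few to test.

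2 lists were called lower in Vkine. Of 27 proliferation genes, 26 had a negative fold change (median -0.38, but -0.25 without Vkine replicate 3 and -0.60 without Vkine replicate 2), with Mcm6 of the replicative helicase at 76.2 CPM ± 7.45 in EV and 47.6 CPM ± 8.74 in Vkine (SD, n = 3). Of 20 macrophage markers, 15 were negative (median -0.19), with Cx3cr1 at 288 CPM ± 26.8 in EV and 160 CPM ± 48.2 in Vkine, C1qa at -0.61 ± 0.23 and Trem2 at -0.51 ± 0.18. No member of either list was called even when adjusted over the list alone. Adjusted p was 1.64e-07 and 0.023, and 0.28 and 0.50 with an estimated correlation. The macrophage call ended without EV replicate 2 (median -0.11, adjusted p = 0.315) or Vkine replicate 3 (-0.08, 0.263). With the replicate block, which in this set compares only R1 with L1 and R2 with L2, neither list was called (0.051 for proliferation and 0.35 for macrophage markers).

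Some markers of cells that a CD45 gate should exclude were also on the higher side. Collagen and matrix fibroblast genes had a median of 0.75 (19 of 20 positive, adjusted p = 3.33e-05, and 0.28 with an estimated correlation), and of 1.38 without EV replicate 1, whose list mean (3.09) exceeded that of Vkine replicate 2 (2.77), with Acta2 at 1.13 ± 0.48. Endothelial markers had a median of 0.56 (14 of 14 positive, adjusted p = 0.0052, and 0.52 with an estimated correlation), a call that ended without EV replicate 2 (0.051), EV replicate 3 (0.186) or Vkine replicate 3 (0.156), with medians of 0.36, 0.28 and 0.10 there and of 1.49 without EV replicate 1. Erythroid genes had a median of 0.93 and epithelial tumour genes of 0.32, and neither was called (0.59 and 0.51). The erythroid rise came from Vkine replicate 1, with a mean log2 CPM of 4.09 against 0.40 and 0.90 in the other Vkine samples and 0.55, 1.80 and 1.90 in EV, and without it the list median was -0.62 (adjusted p = 0.132). The epithelial list overlapped between groups, with 2.31 to 2.92 in EV and 2.72 to 3.23 in Vkine. Its median was -0.09 without EV replicate 3, 0.08 without EV replicate 1 and 0.11 without Vkine replicate 1. B cell markers were not called (median 0.26, adjusted p = 0.79), nor were eosinophil, basophil and mast cell genes (0.38, 0.092, and 0.0328 after the correction for GC content and length described at the end), platelet genes (0.40, 0.055, and 0.0497 after the correction for GC content and length), T cell exhaustion genes (0.37, 0.059), skeletal muscle genes (0.78, 0.157) or the hyaluronan and versican matrix list (0.20, 0.85). Medians of these uncalled lists moved with single libraries: without one in turn they ran from -0.30 (Vkine replicate 1) to 0.74 (EV replicate 1) for B cells and from -0.13 (Vkine replicate 3) to 0.98 (EV replicate 2) for eosinophils, basophils and mast cells. They ran from 0.16 to 0.75 for platelets, 0.25 to 0.75 for T cell exhaustion, 0.37 to 0.97 for skeletal muscle and 0.09 to 0.37 for the matrix list.

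By the edgeR quasi-likelihood test 3 genes were higher and 1 lower among 14006, with 1683 at an unadjusted p under 0.05. In 18.6% of genes the samples of the groups did not overlap, against 10% by chance, and DESeq2 called 176 higher and 39 lower. The 4 genes lost their call without robust estimation and with FPKM. Without Vkine replicate 1 the count was 28, without EV replicate 1 or Vkine replicate 2 it was 1, and without EV replicate 2, EV replicate 3 or Vkine replicate 3 it was 0. The 28 held all 4 genes. The gene called without Vkine replicate 2 was among the 4, and the gene called without EV replicate 1 was not. Of 42 lists tested, 29 were called higher and 2 lower with the preset correlation of camera, and 0 with an estimated correlation. The fry test, which asks whether a list's own genes move on balance in 1 direction, called 0 lists, while its mixed form, which asks whether they change in either direction, called 18. Neither form of fry compares a list with other genes.

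**Figure D1:**
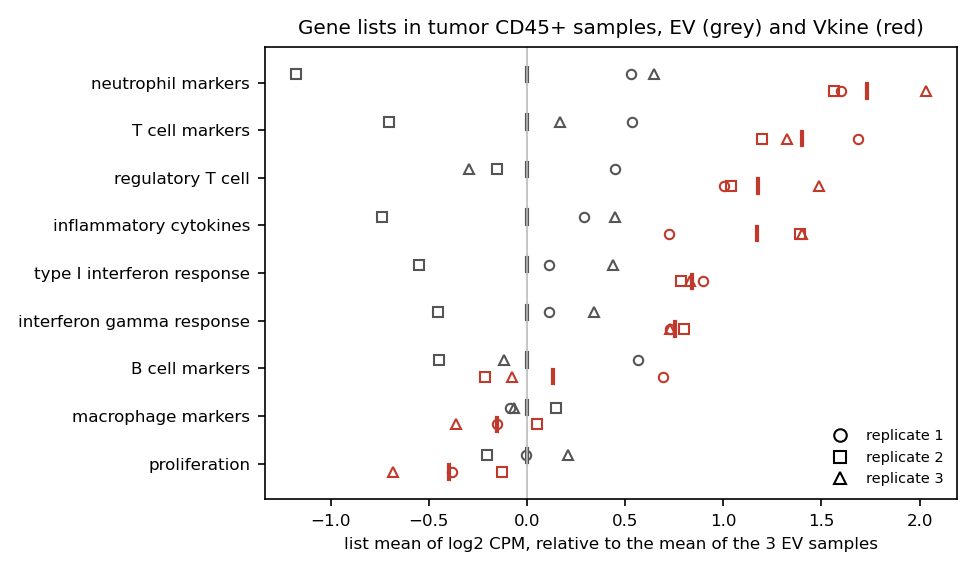
Mean log2 CPM of each gene list in each tumor CD45 sample, relative to the mean of the 3 EV samples, with EV in grey, Vkine in red, 1 symbol per replicate and a bar at the group mean. Neutrophil and T cell markers lie higher in all 3 Vkine samples than in the EV samples, and the groups overlap for proliferation genes.

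In MutuDC, 13357 genes were tested in 1 fit over the 11 samples. The first comparison, Vkine against EV without LPS, asks what versikine does to resting dendritic cells. Immediate early genes, the transcription factors and regulators that cells induce within minutes of stimulation, and enzymes of cholesterol synthesis were the lists with the smallest p. Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273) rose from 26.4 CPM ± 1.19 (SD, n = 2) to 230 CPM ± 14.9 (SD, n = 3), and Egr1 from 55.2 CPM ± 3.75 to 415 CPM ± 49.8. Of 17 immediate early genes 15 rose and 0 fell (median 1.15), with Egr2 at 4.10 ± 0.18 and Zfp36 at 2.47 ± 0.11. Hmgcs1, the HMG-CoA synthase of the pathway (ENSMUSG00000093930, chromosome 13, 119690379 to 119708260), rose from 154 CPM ± 1.71 to 536 CPM ± 23.7, and 20 of 21 cholesterol genes rose and 0 fell (median 1.17), with Insig1, Lss and Msmo1 at 1.57, 1.62 and 1.62. Adjusted p of these lists was 4.53e-46 and 5.66e-48, and 0.0022 and 2.27e-05 with an estimated correlation.

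Inflammatory and interferon genes rose in the same comparison. Of 28 type I interferon response genes 22 rose and 1 fell (median 1.53), including Isg15 (1.8 CPM ± 0.281 to 8.92 CPM ± 0.791), Ifit2 (2.15 ± 0.14) and Ifih1 (1.90 ± 0.14), the last a sensor of viral RNA. Of 24 NF-kB target genes 18 rose and 1 fell (median 0.62), with Nfkbiz at 2.59 ± 0.13, and Tnf, the tumour necrosis factor gene, rose from 1.65 CPM ± 0.669 to 13.7 CPM ± 0.753. Cxcl9 (2.41 ± 0.12), Cxcl10 (3.06 ± 0.20) and Ccl2 (2.60 ± 0.28) rose among 13 chemokines, 7 of which rose and 1 fell. Il1b and Il1a (3.22 and 1.57) were among 8 of 12 inflammatory cytokines that rose, and Cd80 (0.84), Cd83 (0.99) and Lgals9 among 10 of 12 costimulatory and checkpoint ligands. The interferon gamma response list was mixed, with 10 of 20 genes higher and 4 lower, the latter including Irf1 at -1.17. Mature migratory DC genes (9 of 15 higher, 1 lower, median 0.69) and plasmacytoid DC genes (3 of 5 higher, led by Tcf4 at 1.07) were called higher too. Adjusted p of these lists ran from 1.12e-16 to 0.0028, and from 0.00090 to 0.0351 with an estimated correlation.

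Markers of cDC1 cells fell, while cDC2 markers were not called (1 higher and 1 lower of 6, adjusted p = 0.70). Irf8, the transcription factor that cDC1 cells require, went from 4790 CPM ± 59.98 to 3455 CPM ± 69.3 (log2 fold change -0.47 ± 0.06), and Batf3, its partner, from 92 CPM ± 0.526 to 53.9 CPM ± 3.83. Of 18 cDC1 markers 11 fell and 2 rose (median -0.43, adjusted p = 0.00049, and 0.0199 with an estimated correlation), with Naaa and Id2 at -0.61 and -0.74, while Xcr1 rose by 0.30 ± 0.07. Outside these lists Csf1r, the receptor for macrophage colony-stimulating factor (ENSMUSG00000024621, chromosome 18, 61105572 to 61132149), fell from 144 CPM ± 6.87 to 22.2 CPM ± 0.296. Smad9 (-3.10 ± 0.10), Id3 (-2.14 ± 0.11) and Id1 (-1.81 ± 0.11), a mediator and known targets of BMP signalling, were among the genes with the largest decreases. The largest rises were in Fbp2 (5.10 ± 0.24), a fructose bisphosphatase gene, and Cnpy1 (4.75 ± 0.13), which went from 2.15 CPM ± 0.0398 to 58.1 CPM ± 2.

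Lists whose calls were lost with an estimated correlation were ribosomal proteins, glycolysis, oxidative phosphorylation, the NRF2 list, macrophage markers, the integrated stress list, lysosome genes and the study genes (adjusted p = 0.0024, 0.091 with an estimated correlation and 0.0947 after the correction for GC content and length). Cytosolic ribosomal proteins fell in 19 of 25 members (median -0.47, adjusted p = 1.66e-07, and 0.35 with an estimated correlation), with Rps2 at -0.89. Glycolysis genes fell in 15 of 19 (Ldha -0.73, adjusted p = 2.01e-06, and 0.11 with an estimated correlation), and oxidative phosphorylation genes in 11 of 21 (Atp5g1 -0.62, adjusted p = 0.0083, and 0.62 with an estimated correlation). The glycolysis counts are of Ensembl entries, which exceed the symbols of that list, so a symbol with several entries counts more than once here and below. The NRF2 list fell in 7 of 14 and rose in 2 (Hmox1 -1.08, adjusted p = 0.0056, and 0.11 with an estimated correlation). Lysosome genes rose in 13 of 21 (Ctsd 1.70, adjusted p = 0.00080, and 0.089 with an estimated correlation), and the unfolded protein and integrated stress list in 9 of 20 with 4 lower (Trib3 2.67, Asns 1.09, adjusted p = 0.00051, and 0.21 with an estimated correlation). Proliferation genes were not called (4 higher and 6 lower of 27, adjusted p = 0.73), and the sign of their median turned with upper-quartile scaling and with FPKM.

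In all, 2261 genes were higher and 2446 lower, 562 and 217 of them by more than 2-fold, and 20 lists were called, of which 12 held with an estimated correlation. EV had 2 samples: the count of 4707 was 2748 without EV replicate 1 and 2906 without EV replicate 2, where the lone EV sample is assumed to vary like the other groups. Fold changes followed the GC content of genes in this comparison (Pearson r = -0.27 across genes, which are not replicates), and the split was 1941 higher and 3469 lower after the correction for GC content and length, while with FPKM the share of higher genes went from 48.0% to 62.1%.

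LPS in EV cells, the reference response of the line, raised interferon, chemokine and maturation genes. Cxcl9, a chemokine for activated T cells (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079), rose from 4.15 CPM ± 0.285 (SD, n = 2) to 88 CPM ± 6.35 (SD, n = 3), and Isg15 from 1.8 CPM to 27.6 CPM ± 5.27. Of 28 type I interferon response genes 26 rose and 0 fell (median 2.58), with Usp18 and Oasl2 at 2.44 and 2.57. Ccl22, a chemokine of mature dendritic cells (ENSMUSG00000031779, chromosome 8, 94745590 to 94751699), rose from 18.4 CPM ± 0.155 to 122 CPM ± 5.82, and Cd40, a costimulatory receptor (ENSMUSG00000017652, chromosome 2, 165055627 to 165072948), from 19.4 CPM ± 0.885 to 67 CPM ± 5.75. Of 24 NF-kB target genes 19 rose and 1 fell, of 13 chemokines 11 rose and 1 fell, and of 15 mature migratory DC genes 12 rose and 0 fell (medians 1.06, 2.16 and 1.02). Interferon gamma response genes (13 of 20 higher, median 1.79, led by Cxcl9) and costimulatory ligands (8 of 12 higher, Lgals9 at 2.88) were called as well. Inflammatory cytokines rose in 10 of 12, Il1b by 3.72 ± 0.38. Each of these lists was called (largest adjusted p 4.69e-08, and 0.036 with an estimated correlation).

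LPS also raised cholesterol synthesis genes in EV cells, 18 of 21 (median 0.87, adjusted p = 2.57e-23, and 0.00015 with an estimated correlation), with Idi1 at 1.55 and Hmgcs1 at 1.39. Immediate early genes were called lower, unlike with Vkine: 9 of 17 fell and 3 rose, Fos going from 26.4 CPM to 11.8 CPM ± 1.44 while Ier3 rose by 2.58 (adjusted p = 0.0014, and 0.24 with an estimated correlation). The NRF2 list fell in 8 of 14 (adjusted p = 6.33e-05, and 0.0404 with an estimated correlation), with Hmox1, the haem oxygenase gene, at -1.75 ± 0.08. Class I presentation genes rose in 12 of 19, with B2m at 1.23 and H2-Q6 and H2-Q7, whose reads may be shared, at 1.86 and 2.05 (adjusted p = 1.34e-11, and 0.092 with an estimated correlation). Ifi204 (4.12 ± 0.11) and Slfn5 (3.73 ± 0.14) followed Cxcl9 among the largest rises, Ifi204 belonging to a family of near-identical genes. Glycolysis genes fell in 11 of 19 (0.22 with an estimated correlation). Irf8 fell by 0.31 ± 0.06 and Xcr1 rose by 0.53 ± 0.07, and the cDC1 list was not called (2 higher, 7 lower of 18, adjusted p = 0.26), although after the correction for GC content and length it was called lower (median -0.18, adjusted p = 0.0011).

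In this comparison 2294 genes were higher and 2355 lower, 455 and 239 by more than 2-fold, and 16 lists were called, 11 of them also with an estimated correlation. The count of 4649 was 2736 without EV replicate 1, 2778 without EV replicate 2 and 3016 when the fit held the compared groups alone. Fold changes followed GC content (Pearson r = -0.32 across genes), and the split was 1760 higher and 2372 lower after the correction and 2528 and 1990 with FPKM.

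LPS in Vkine cells raised chemokine, NF-kB and interferon genes. Ccl22 rose from 21 CPM ± 1.91 to 992 CPM ± 18.2 (SD, n = 3), a log2 fold change of 5.56 ± 0.08, and Cd40 from 27.9 CPM ± 1.06 to 204 CPM ± 6.78. Nrp2 (4.52 ± 0.11), the complement gene C3 (4.38 ± 0.24) and Adgre1 (3.81 ± 0.13), which encodes the macrophage antigen F4/80, also rose. Of 24 NF-kB target genes 21 rose and 0 fell (median 1.38), with Tnip1 and Nfkb2 at 2.21 and 1.44, and 9 of 13 chemokines rose and 1 fell, with Ccl17 at 6.46 ± 0.40 from a level under 1 CPM and Ccl3 at 3.40. Interferon gamma genes rose in 18 of 20 (Gbp2 3.15, Tap1 1.12), type I interferon genes in 25 of 28 (median 1.16, Oasl1 2.09, Mx1 1.53) and class I presentation genes in 17 of 19 (Tapbpl 1.10). Il12b (4.29 ± 0.60) and Tlr2 (4.01 ± 0.40) rose, and so did Irf8 (0.37) and Batf3 (0.86). Each of these lists was called (largest adjusted p 4.75e-10), and with an estimated correlation each held (largest 0.0023) except class I presentation (0.14).

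Immediate early and cholesterol genes moved the other way in Vkine cells given LPS. Of 17 immediate early genes 12 fell and 1 rose (median -0.93), with Fos at 30.9 CPM ± 1.02 after 230 CPM and Fosb at -4.97 ± 0.17. Of 21 cholesterol genes 17 fell and 0 rose (median -0.58), with Nsdhl at -1.14 and Hmgcs1 at 299 CPM ± 17.8 after 536 CPM. Adjusted p was 1.12e-20 and 2.11e-10, and 0.0091 and 0.0010 with an estimated correlation. Cnpy1 (-5.28 ± 0.11), Fbp2 (-4.87 ± 0.19), Scd1 (-2.79 ± 0.09), a fatty acid desaturase gene, and Lpin1 (-2.55 ± 0.08) were the other large decreases. Ribosomal proteins rose in 24 of 25 (median 0.73, Rps2 1.04), oxidative phosphorylation genes in 15 of 21 (Cox7a2 0.70) and glycolysis genes in 14 of 19 (Hk2 0.84), with adjusted p of 2.71e-09, 0.0017 and 0.0037, and 0.29, 0.48 and 0.29 with an estimated correlation.

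The count was 3691 higher and 3240 lower, 605 and 756 by more than 2-fold, with 18 lists called and 9 of them also with an estimated correlation. Against a fold of 1.5 the test called 1271 genes. Fold changes followed GC content (Pearson r = 0.22 across genes), with 4094 higher and 3048 lower after the correction. The share of higher genes was 53.3%, and 39.0% with the deposited FPKM on a log2 scale with 1 added, where the median log2 fold change of all genes was -0.08.

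Vkine against EV under LPS, the comparison of activated cells, showed higher NF-kB, chemokine and maturation genes in Vkine. Ccl22 was at 992 CPM ± 18.2 against 122 CPM ± 5.82 (SD, n = 3), Cd40 at 204 CPM ± 6.78 against 67 CPM ± 5.75 and Cxcl9 at 249.7 CPM ± 12.2 against 88 CPM ± 6.35. Of 24 NF-kB target genes 22 were higher and 0 lower (median 1.47), with Tnfaip2 (1.41 ± 0.06), Tnip1 (1.66 ± 0.07) and Icam1 (1.38 ± 0.06), an adhesion molecule. Of 13 chemokines 12 were higher and 0 lower (median 1.65), with Ccl3 at 3.01 and Ccl17 at 2.67, and of 15 mature migratory DC genes 9 were higher and 0 lower, with Fscn1, an actin bundling protein, at 1.38 and Relb at 1.02. Adjusted p of these 3 lists was 9.47e-47, 1.11e-22 and 3.29e-13, and 0.0010, 0.0022 and 0.0012 with an estimated correlation. The lists share members, such as Ccl3 (NF-kB and chemokines), Relb (NF-kB and mature DC) and Ccl22 (chemokines and mature DC). Among cytokines Il1b (2.53 ± 0.18), Tnf (1.79 ± 0.13), Ebi3 (1.86 ± 0.17) and Il12b (2.37 ± 0.47) were higher and Il18 (-0.64 ± 0.12) lower (list adjusted p = 0.0017, 0.15 with an estimated correlation and 0.0521 after the correction for GC content and length).

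Immediate early genes were higher with Vkine under LPS too, 13 of 17 with 0 lower, with Egr1 at 91.7 CPM ± 1.97 against 28.9 CPM ± 0.359 and Junb at 1.58 ± 0.11 (adjusted p = 6.1e-13, and 0.03 with an estimated correlation). Interferon gamma response genes were higher in 12 of 20 (Serpina3g 1.58, Gbp2 1.68, 0.0105 with an estimated correlation), the first of these having close paralogs. The type I interferon list was not called (5 higher, 4 lower of 28, adjusted p = 0.56), its median of -0.01 having the opposite sign to its mean and test. Cholesterol genes were lower in 11 of 21 and higher in 3 (Idi1 -0.65, adjusted p = 0.0063, and 0.0372 with an estimated correlation). Scd1 (-2.23 ± 0.09) and the cholesterol exporter genes Abca1 (-1.74 ± 0.19) and Abcg1 (-1.35 ± 0.07) were among the largest decreases. The NRF2 list was higher in 9 of 14 (Hmox1 1.42) and p53 target genes in 8 of 14 with 2 lower (Cdkn1a 1.49), at 0.0345 and 0.0372 with an estimated correlation. The cDC1 list was not called (5 higher and 5 lower of 18, adjusted p = 0.71). Ribosomal proteins were higher in 13 of 25 (adjusted p = 0.0113, and 0.76 with an estimated correlation), a call that ended without EV LPS replicate 2 (0.227).

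In this comparison 3043 genes were higher and 2563 lower, 401 and 340 by more than 2-fold, with 16 lists called and 12 of them also with an estimated correlation. Fold changes followed GC content (Pearson r = 0.34 across genes), with 2691 higher and 2547 lower after the correction. Against a fold of 1.5 the test called 484 genes, and with FPKM the share of higher genes went from 54.3% to 42.8%.

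**Figure D2:**
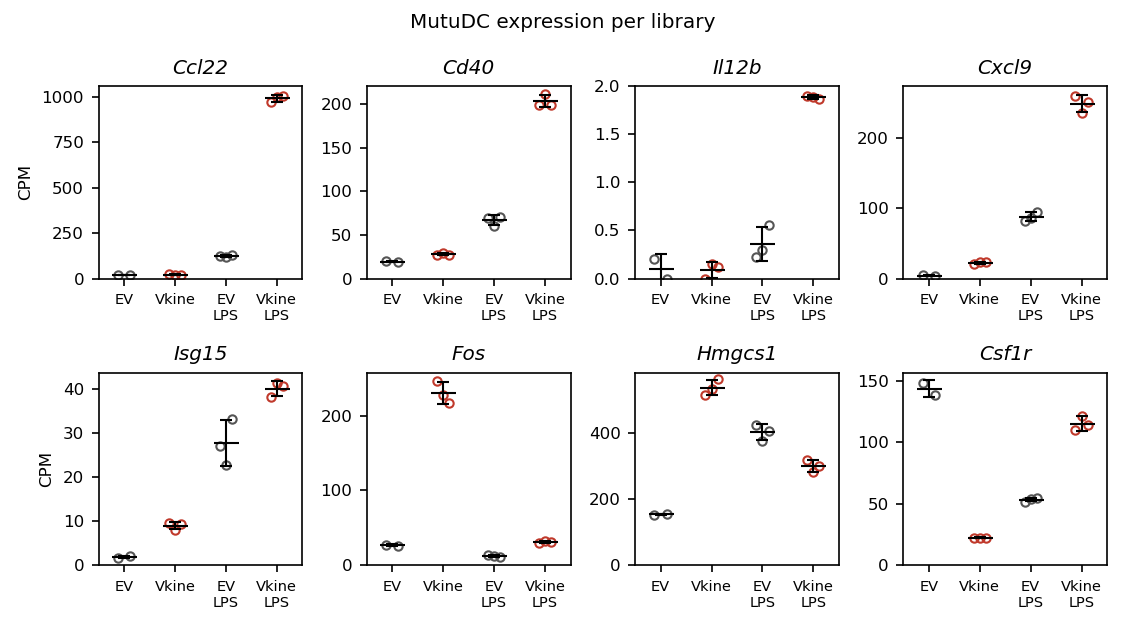
CPM of 8 genes in each MutuDC library, with points for libraries and bars for the mean and SD of each group (n = 2 for EV, 3 for the others). Ccl22, Cd40 and Cxcl9 are highest with Vkine and LPS together, Fos and Hmgcs1 with Vkine alone, and Csf1r in EV.

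The interaction asks whether the effect of Vkine differed with LPS, as the difference between both Vkine effects. It was negative for cholesterol synthesis, where 18 of 21 genes had a lower effect and 1 a higher one (median -1.53), with Hmgcs1 at -2.23 ± 0.10, Idi1 at -2.26 ± 0.11 and Msmo1 at -2.15 ± 0.11. It was negative for type I interferon genes as well, 20 of 28 with 4 positive (median -1.27), with Ifit2 at -2.05, Ifih1 at -1.91 and Stat2 at -1.07, while Oasl1 went to 1.81 ± 0.10. These were the lists whose call held with an estimated correlation, with adjusted p of 1.53e-26 and 4.82e-07, and 0.00017 and 0.0124 with an estimated correlation. Csf1r had the reverse course, 144, 22.2, 53.2 and 115 CPM in EV, Vkine, EV with LPS and Vkine with LPS, an interaction of 3.81 ± 0.10. Smad9 went with it (52.2, 6.05, 24.3 and 41.9 CPM, 3.89 ± 0.13), and Cx3cl1, the ligand of Cx3cr1, had 3.76 ± 0.21. Scd1 (-4.87 ± 0.13), Lpin1 (-4.25 ± 0.13) and Cnpy1 (-5.30 ± 0.21) were the largest in the other direction.

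Maturation genes divided. Ccl22 (2.83 ± 0.11), Cd40 (1.08 ± 0.11), Fscn1 (1.55 ± 0.19) and the NF-kB targets Icam1 (1.61 ± 0.09) and Tnfaip2 (1.29 ± 0.08) had a positive interaction, whereas Tnf (-1.23 ± 0.25), Cxcl10 (-2.06 ± 0.24), Il1a (-2.07 ± 0.16) and Cd83 (-0.77 ± 0.10) had a negative one. The lists that hold them were not called (NF-kB targets adjusted p = 0.068, mature migratory DC 0.60, chemokines 0.60), and the mature migratory DC median of -0.24 had the opposite sign to its mean and test. Glycolysis (17 of 19 positive, Pfkp 1.03), ribosomal proteins (19 of 25, Rpl11 1.49), the NRF2 list (9 of 14, Hmox1 2.50), immediate early genes (9 of 17 negative, Fos -1.74) and plasmacytoid DC genes (4 of 5 negative) were called with the preset correlation, and had adjusted p of 0.32, 0.72, 0.11, 0.32 and 0.25 with an estimated correlation. The plasmacytoid call (0.044) also ended without EV replicate 1 (0.0532), EV LPS replicate 3 (0.0799) or Vkine LPS replicate 1 (0.0526). Irf8 (0.68 ± 0.08) and Batf3 (1.27 ± 0.14) were positive, and the cDC1 list was not called (median 0.47, adjusted p = 0.117), although after the correction for GC content and length it was called positive (median 0.52, adjusted p = 0.00047).

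The interaction was called in 6577 genes, 3409 positive and 3168 negative, 1002 and 1148 of them by more than 2-fold, and 2162 passed against a fold of 1.5. Fold changes of the interaction followed GC content (Pearson r = 0.38 across genes), with 3631 positive and 2648 negative after the correction, and with FPKM the share of positive genes went from 51.8% to 38.9%, with a median of all genes of -0.12 against -0.02.

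Genes called for Vkine without LPS and with LPS overlapped less than chance in each direction. Of 2261 and 3043 genes called higher 284 were shared, against 515 expected (Fisher's exact test, two-sided, p = 7.18e-41), and of 2446 and 2563 called lower 97 were shared, against 469 expected (p = 1.55e-128). 988 genes were higher without LPS and lower with it, and 1449 the reverse, so that 2437 were called in opposite directions. Among the largest changes opposite effects did not prevail: of genes over 4-fold in both comparisons, 18 went in the same direction and 15 in opposite ones. Pearson r of both fold changes was -0.26 across 13357 genes, which are not independent replicates. Fisher's exact test takes them as independent, so its p-values here do not measure the spread between samples. Cxcl9, Il1b, Tnf and Fos were higher in both, Scd1, Lpin1 and Hmgcs1 were higher without LPS and lower with it, and Csf1r and Smad9 were lower without LPS and higher with it. The LPS responses of EV and Vkine cells shared 532 higher genes (634 expected, p = 1.23e-07) and 369 lower genes (571 expected, p = 1.01e-28), with 1971 in opposite directions and r = 0.05. With DESeq2 the shared counts were 256 and 87 for Vkine and 492 and 340 for LPS.

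**Figure D3:**
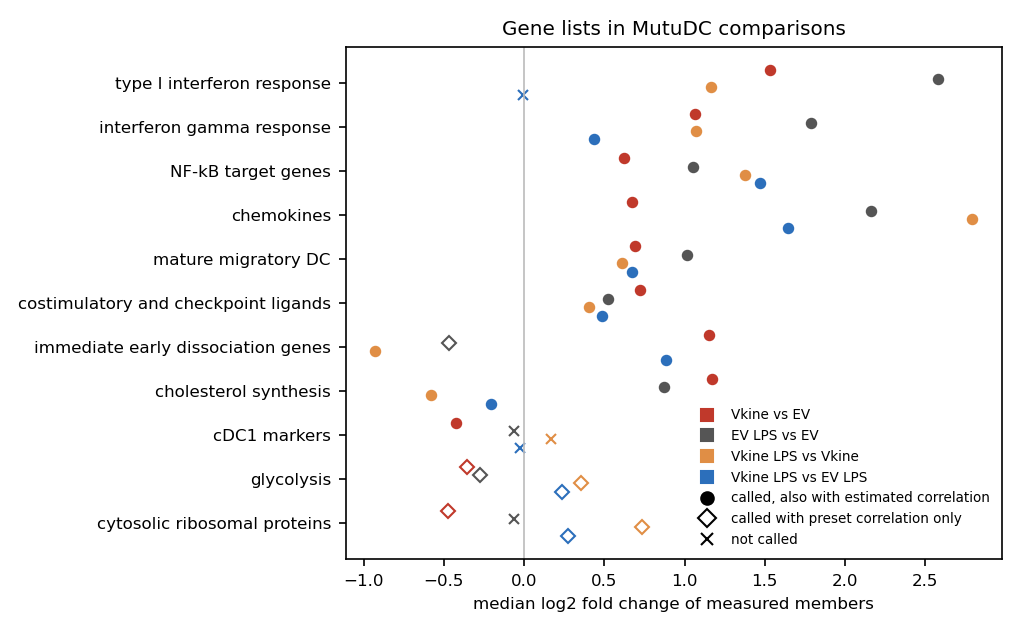
Median log2 fold change of the measured members of each list in 4 MutuDC comparisons, with filled circles for lists called also with an estimated correlation, diamonds for lists called with the preset correlation alone and crosses for lists not called. Type I interferon genes lie highest with LPS in EV cells (2.58), and cholesterol genes are positive for Vkine and for LPS alone (1.17 and 0.87) and negative for LPS in Vkine cells (-0.58).

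**Figure D4:**
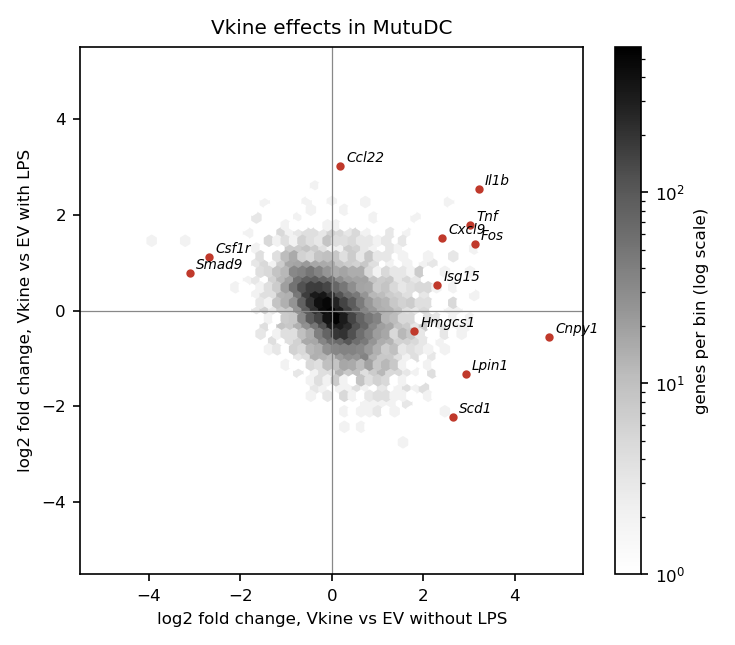
Log2 fold change of Vkine against EV without LPS (horizontal) and with LPS (vertical) for 13357 genes in MutuDC, with shading for genes per bin on a log scale and red points for 12 labelled genes. The effects are inversely related across all genes (r = -0.26), with Cxcl9 and Tnf higher in both. Of genes over 4-fold in both comparisons 18 lie in the same direction and 15 in opposite ones.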

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

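The test without Vkine replicate 1, the contrasts with B cell markers and the exchange of labels were chosen after the results they measure had been seen.

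The difference between the Vkine effects with and without LPS, tested directly in MutuDC by the interaction, passed in 6577 genes. Among named genes it was 3.89 for Smad9, 3.89 for Bcl2a1b, which has close paralogs, 3.81 for Csf1r, 3.76 for Cx3cl1 and 3.64 for Atp5k on the log2 scale. It was -5.30 for Cnpy1, -4.87 for Scd1, -4.25 for Lpin1, -3.33 for Ifitm6 and -3.26 for Hpgds. The list medians were -1.27 for type I interferon response genes and -1.53 for cholesterol synthesis.

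The inverse relation of the Vkine effects in MutuDC remains open between technical and biological explanations. After a correction for GC content and transcript length, Pearson r across genes went from -0.26 to -0.193, genes called in opposite directions from 2437 to 2195 and genes called in the same direction from 381 to 620, so such a trend could account for part of it. Had the EV and Vkine labels been exchanged among the cultures without LPS, EV with LPS against the cultures labelled Vkine would be an LPS effect: 3 of 24 NF-kB target genes were lower and 12 higher, with fold changes of -1.23 for Tnf, -2.32 for Cxcl2 and -2.28 for Ccl2 but 0.50 for Il1b, 1.26 for Cd40 and 2.54 for Ccl22. Genes over 4-fold in both Vkine comparisons were 18 in the same direction and 15 in opposite ones, counts that an exchange would swap. The LPS responses of both arms correlated at 0.05 as labelled and at 0.31 with those labels exchanged. The covariance behind the 0.31 is fixed by those of the LPS responses as labelled and of both Vkine effects. It restates the inverse relation and is no separate sign of an exchange. A label error and a true reversal of the Vkine effect by LPS cannot be told apart, since Vcan (0.325 to 0.993 CPM by group) does not mark the Vkine cultures. A biological difference in how Vkine acts on activated cells stays open and untested.

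The rise of immediate early and cholesterol genes in MutuDC with Vkine and no LPS was kept after the correction for GC content and length, the lower of the list medians being 0.97. The correction turned the split of called genes from 2261 higher and 2446 lower into 1941 and 3469. List tests after it used camera on log2 CPM instead of counts, so changed list calls may in part reflect the test and not the correction. Over all comparisons 8 of 108 list calls were lost, none of them of these lists or of the interaction: study genes for Vkine without LPS (adjusted p = 0.0947), cDC2 markers (0.371), macrophage markers (0.146) and inflammatory cytokines (0.276) for LPS in Vkine, and cDC2 markers (0.0519), inflammatory cytokines (0.0521), the toll-like receptor pathway (0.115) and glycolysis (0.0623) for Vkine under LPS. Of 74 others 9 gained a call: cDC1 markers lower for LPS in EV (0.0011) and higher for LPS in Vkine (0.0058) and in the interaction (0.00047), where oxidative phosphorylation (0.00066) was higher and lysosome genes (0.0301) lower, heat shock genes lower for Vkine without LPS (0.0456), proliferation lower for Vkine under LPS (0.042), and eosinophil, basophil and mast cell genes (0.0328) and platelet genes (0.0497) higher in tumor CD45 cells. The smaller of the gaps between the lowest Vkine and the highest EV library was 14.3 SDs of the Vkine libraries (49.5 for cholesterol genes), which does not argue against handling that differed from culture to culture, since the labels do not say that replicates are separate cultures and the lists were picked for this difference. Handling, growth state or harvest time shared by a whole group is confounded with Vkine and could still account for these genes, as could Vkine itself, and the gap of 14.3 SDs does not separate them.

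The lists called higher in tumor CD45 cells with Vkine, most of them immune, did not follow GC content or length (r = 0.000714 and -0.00871 with the fold changes), which left little trend to remove, and 29 of 29 lists were called higher after the correction. Without Vkine replicate 1, the library rich in mitochondrial reads, 27 of 29 lists were still called higher. Both counts rest on the preset correlation, with which other groupings of these 6 samples also called 6 to 22 lists. They therefore do not exclude differences between single samples as a cause. A lower share of macrophages would raise the markers of all other cell types alike. The neutrophil list rose by 1.60 (SE 0.56) more than the B cell list and the T cell list by 1.27 (SE 0.21) more, at least 1.91 and 4.16 SEs without any 1 library. These lists were set against each other after their medians (1.62, 1.29 and 0.26 for B cells) had been seen, so a gap was built into the choice. The B cell median also ran from -0.30 to 0.74 without single libraries. The gaps therefore do not decide whether a lower macrophage share is the whole cause for these 2 lists. T cell markers lay at low levels, which limits the T cell contrast. NK cell markers (0.54, SE 0.37), monocyte markers (0.32, SE 0.48) and cDC1 markers (0.41, SE 0.34) rose by at most 1.46 SEs more, so for them too a lower macrophage share stays open. These gaps hung on single libraries: NK reached 3.22 SEs without EV replicate 2, and without Vkine replicate 1 the rise of monocyte markers was 0.75 (SE 0.22) more and that of cDC1 markers 0.69 (SE 0.24) more. A larger share of neutrophils and T cells, activation within cells, or carry-over of non-immune cells that differed between sorts may each contribute, and the 1.60 does not tell them apart, nor does it tell how far lists move together by sample alone, since none was called with an estimated correlation.

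The 10 splits of 6 samples into 3 and 3 are too few for a share under 0.05. In tumor CD45 cells the real split called 4 genes and the highest other 0, and 31 lists against 22, with 1 split, the real one, at the real value. At an unadjusted p under 0.05 by the edgeR test the real split had 1683 genes, and the others had from 128 to 1399. In fits of the compared groups alone, LPS in Vkine cells gave 7705 genes against 0 and 18 lists against 12, and Vkine under LPS gave 4679 genes against 0 and 15 lists against 14.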

How the results depend on the processing

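All alternatives below were planned. In tumor CD45 cells the count of 4 genes was 4 with median-of-ratios factors and 3 with upper-quartile factors or the stricter filter, 511 (415 higher, 96 lower) without a low-count filter, 215 (176 and 39) with DESeq2, and 0 without robust estimation, with a replicate block, against a fold of 1.5 and with FPKM plus 1 or 0.1, beside 1683 genes at an unadjusted p under 0.05. Leaving out samples gave 0 to 28, with 28 without Vkine replicate 1, 1 without EV replicate 1 or Vkine replicate 2, and 0 without EV replicate 2, EV replicate 3 or Vkine replicate 3. The gene called without EV replicate 1 was none of the 4. The smallest adjusted p, 0.042, lay close to the threshold, and the cause of the larger changes was not tested. Against a fold of 1.5 the MutuDC counts were 553 for Vkine without LPS, 490 for LPS in EV, 1271 for LPS in Vkine, 484 for Vkine under LPS and 2162 for the interaction, a stricter question by construction. Leaving out samples gave 2748 to 4376 genes for Vkine without LPS and 2736 to 5640 for LPS in EV, both lowest without EV replicate 1 (2906 and 2778 without EV replicate 2), where the lone EV sample is assumed to vary like the other groups. It gave 5851 to 6380 for LPS in Vkine, 4335 to 5974 for Vkine under LPS and 5321 to 7077 for the interaction. With the compared groups alone LPS in EV had 3016 genes, from 5 samples. The other alternatives left the MutuDC counts within 1.5 times those reported, the replicate block giving 4130, 3919, 6673, 5250 and 6142. In tumor CD45 cells 26 lists were called with the replicate block, all higher, and 25 of them were among the 31 called without it. With an estimated correlation 0 lists were called in tumor CD45 cells, 12 for Vkine without LPS, 9 for LPS in Vkine and 2 in the interaction. The directional fry test called 0 lists in tumor CD45 cells and 20 in the interaction, and its mixed form 18 in tumor CD45 cells, 27 for LPS in EV, 28 for LPS in Vkine, 27 for Vkine under LPS and 28 in the interaction, fry asking another question than camera. The replicate numbers, which in tumor CD45 cells follow the order of the samples and not their titles, did not pair samples: residuals of samples with the same number correlated at -0.10 to 0.10 in MutuDC and -0.05 to 0.04 in tumor CD45 cells, and 0 of 15 MutuDC pairs were above 0.1. EV sample R1L1 (replicate 3 here) correlated at -0.02 with Vkine sample L1. With FPKM plus 1 the share of higher genes went from 48.0% to 62.1% for Vkine without LPS, 53.3% to 39.0% for LPS in Vkine, 54.3% to 42.8% for Vkine under LPS and 51.8% to 38.9% in the interaction. The MutuDC FPKM hold no factor per sample beyond the column total, so this alternative leaves out TMM. TMM factors moved with group: 0.98 and 0.99 in EV, 1.04 to 1.05 in Vkine, 0.99 to 1.03 in EV with LPS and 0.95 to 0.97 in Vkine with LPS. Whether this accounts for the whole shift was not tested. No list called with the preset correlation changed the sign of its median under the other scalings (108 calls), and 11 of 74 uncalled lists did. No named gene reversed, and of 613 pairs of called named gene and MutuDC comparison 358 kept their call under every alternative, the test against a fold of 1.5 included, while the 4 genes called in tumor CD45 cells each lost it under at least 1. The spread between replicates exceeded counting error in every pair of replicates (chi-square per degree of freedom of 2.49 or more), so no 2 samples of the same group looked like 1 library deposited again. Pairs across groups were not compared. Depth limits what can be said of genes under the low-count filter, which left 14006 genes in tumor CD45 cells and 13357 in MutuDC of 54532.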

Other observations

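Both tests of hypotheses below were chosen before their results were seen.

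Some genes better known from macrophages, C1qa, Ms4a7 and Adgre1 among them, rose in the dendritic cell line with either stimulus. Csf1r, of the same list and more abundant in EV than these genes, was lower with Vkine and with LPS in EV cells. C1qa, a complement subunit gene, averaged 6.22, 28.2, 22.9 and 42.1 CPM in EV, Vkine, EV with LPS and Vkine with LPS, and Ms4a7 averaged 0.303, 5.26, 3.42 and 7.05 CPM. Adgre1 went from 1.03 and 2.81 CPM without LPS to 8.61 and 39.8 CPM with it. Of 12 macrophage markers 8 rose and 2 fell with Vkine (adjusted p = 0.0024, and 0.15 with an estimated correlation), 8 rose and 1 fell with LPS in EV cells (2.92e-05 and 0.074), and 7 rose and 1 fell with Vkine under LPS (4.91e-07 and 0.0372).

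Stress genes in tumor CD45 cells lay on the higher side with Vkine. Hypoxia response genes had a median of 0.62 (adjusted p = 6.88e-07, and 0.20 with an estimated correlation), with 8 of 16 called adjusted over the list alone, among them Ndrg1 (0.76 ± 0.18) and Ero1l (1.09 ± 0.29). All 14 NRF2 genes were positive (median 0.48), with Osgin1 at 1.32 and Fth1 at 0.90, and 9 of 12 heat shock genes were positive, with Dnajb1 at 0.79 ± 0.16. Adjusted p was 5.61e-06 and 0.0015, and 0.25 and 0.28 with an estimated correlation. The NRF2 mean in Vkine replicate 1 (log2 CPM 7.58) lay within the EV samples (6.81 to 7.61). Immediate early genes, which tissue dissociation also induces, were called higher as well (14 of 17 positive, median 0.25, adjusted p = 0.0158, and 0.52 with an estimated correlation). That call ended without EV replicate 2 (median 0.07, adjusted p = 0.43) or Vkine replicate 3 (0.08, 0.091), and the median was 0.40 without EV replicate 3 and 0.41 without Vkine replicate 2. Hyaluronan and versican matrix genes were not called in MutuDC with Vkine (adjusted p = 0.65), yet Hapln3, a link protein gene, went from 0.565 to 3.96 CPM and fell to 0.233 CPM in Vkine cells with LPS.

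A shared Vkine response in tumor CD45 cells and in MutuDC without LPS was tested as a hypothesis. Pearson r of the fold changes was 0.157 across 11700 genes, and the highest absolute value among the other splits of the CD45 samples was 0.130. With 10 splits the share is never under 0.05, so whether the same genes respond may not be read from r = 0.157.

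That genes responding to LPS also move with Vkine alone was tested against the correlation that shared EV libraries create. The covariance of both fold changes was 0.249 and the mean in 20 simulations with shared controls and no effect was 0.0438 (highest 0.0474), a difference of 0.205. Pearson r was 0.58, below the simulated mean of 0.61. The excess of 0.205 is consistent with Vkine moving part of the LPS response of this line, but the 2 EV libraries cannot be split, so a shift they share with no other group could contribute. Both effects are taken over the libraries labelled EV, so if the labels without LPS had been exchanged, the 0.205 would not measure Vkine over its control.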
